A study of Mus musculus with 4 samples.

How the data were processed

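Gene expression was measured in XCR1+ dendritic cells sorted by flow cytometry from mouse spleen, on 1-colour oligonucleotide gene arrays hybridised with biotin-labelled material. Per the labels' protocols, RNA came from a column kit for small samples (RNeasy Plus Micro), and probes were made through 2 rounds of amplification with NuGEN kits. Amplification from few cells can compress or distort the levels of single genes, and it was applied to both groups. The deposited values are log2 expression values, 1 per probe set and array, made with RMA in the oligo package per the submitters' processing notes, with no version given. RMA subtracts background, makes the distributions of the arrays equal by quantiles and summarises the probes of each probe set, so a difference in total RNA per cell cannot be seen in these values. Which arrays were normalized together is not given in the sources used here. The medians of the 4 arrays were not identical. This does not tell whether further arrays were normalized with them, since RMA equalises the arrays before the probes are summarised. Normalizing the 4 arrays again was one of the alternatives. No columns of other samples were present (0).

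Each array was assigned to its group by the treatment label, giving 2 untreated arrays and 2 arrays from 1.5 days after infection with MCMV. The values of no pair of arrays were identical beyond 81 to 108 of the 35556 probe sets, so no array was a copy of another. Probe sets were named through the platform annotation, which pairs 21789 with 1 gene symbol, 1621 with several and 12146 with none here. Only probe sets with 1 symbol were named. Of these, 21698 were matched by gene identifier to a RefSeq gene table of assembly GRCm38.p6, used for names only, which changed 0 symbols. No genome build is given in the sources used here, so no positions are printed. Of the 999 genes with several probe sets, the probe set with the highest mean over the 4 arrays was used, and no gene had 1 probe set called up and another called down. The table holds no detection calls. The median of the probe-set means was 4.83, and values below it are not told from background, so folds against such values are likely to understate a change. No filter on low values was applied in the fit reported first.

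The comparison, MCMV minus untreated, was fitted with lmFit and eBayes in limma 3.58.1 under R 4.3.3, without a trend or robust setting, and 2-sided p-values were adjusted over the 19938 genes by the Benjamini-Hochberg method. All adjusted p-values of genes come from this fit unless another setting is named. The fit had 2 residual degrees of freedom per gene and borrowed 4.14 more from all genes, around a prior SD of 0.09 on the log2 scale. The number of arrays limits the precision: the smallest log2 difference that passed was 0.29. Standard errors are limma's, and SDs are those of the 2 arrays of a group. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 25 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way without comparing them to other genes, were run beside it. With an estimated correlation camera has only the 2 residual degrees of freedom, and 0 of the 18 list calls held. The lists were 17 of pathways and 8 of markers of other cells. Of their 448 genes 404 were measured, the rest sharing a probe set with another symbol or having none named here. A gene can stand in several lists. Because the markers of a list were chosen from general knowledge, the sorted cells may express some of them themselves.

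Choices made before the data were examined were the test, the lists, 24 chosen genes, the alternatives and the rule for named genes. The rule took the 10 rising and 10 falling genes of largest log2 difference among those past an adjusted p of 0.05 with groups that do not overlap, leaving out predicted models, clone names, receptor segments and small RNAs. To these it added the chosen genes, up to 3 members of each list past the threshold with the largest differences, the brightest member not past it, and the 2 brightest markers of each other cell type. Where a list had 5 or fewer members in a direction, members outside the rule were named as well and are marked as chosen after their values were seen. Of the chosen genes 22 were measured. Isg15 shares its probe set with another symbol. Rigi is named Ddx58 in the annotation.

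The alternatives were leaving out each array in turn, where the group left with 1 array is assumed to vary like the other, the replicate number as a block, quantile normalization, centring on the median, cyclic loess, filters at the array median and at the 75th percentile in at least 2 arrays, the mean of a gene's probe sets, all probe sets singly, other variance models, array weights, other thresholds and other list tests. The fit was tested in 20 runs on simulated data for 19938 genes, of which 200 were changed, fewer than the 2544 that passed in the data. Variances were drawn from limma's fitted prior and genes varied independently, so the rates hold only under limma's own model. The fit recovered 15.9% of genes changed by 0.5 on the log2 scale, 93.2% of those changed by 1 and 99.2% of those changed by 2. Of its calls 5.17% were false, and 0 had the wrong sign. Camera found 100% of the lists shifted by 0.5 and called 3.85% of unshifted lists. The simulated genes were uncorrelated, while the correlation estimated in the data reached 0.631 for cell cycle genes, so these rates do not cover correlated lists. The labels number the arrays of each group, without saying that a number marks a shared day or litter.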

Results

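XCR1+ dendritic cells are the dendritic cells specialised in taking up dead cells and presenting their antigens to CD8 T cells, and XCR1 is a chemokine receptor on their surface. The series compared these cells between untreated wild-type C57BL/6 mice and mice infected intraperitoneally with murine cytomegalovirus (MCMV), a mouse herpesvirus, 1.5 days before. The cells were sorted from spleen as lineage-negative, CD11c-high, CD11b-negative and CD8α-positive, and the labels call the cells of infected mice infection-matured. Each group held 2 arrays, and each array gave 35556 deposited probe-set values on a log2 scale. Median values were 4.82 and 4.85 on the untreated arrays and 4.85 and 4.78 on the MCMV arrays. Across probe sets, Pearson's r was 0.993 between the untreated arrays, 0.994 between the MCMV arrays, and 0.983 to 0.984 between arrays of different groups. Probe sets are not independent replicates, so these values describe the arrays and carry no test. The first principal component held 84% of the variance and separated the groups. The labels do not say whether the arrays of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

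The question was which genes differed in XCR1+ dendritic cells between infected and untreated mice. Predicted models, clone names and receptor segments left aside, the largest rise was that of Slfn1 (probe set 10379633), a Schlafen gene induced by interferon, which went from 4.21 ± 0.05 to 9.43 ± 0.02 (SD, n = 2). Its difference of 5.22 on the log2 scale (SE 0.08) is 37.2-fold, with a limma adjusted p of 8.21e-06. The next rises were those of Ifit2, Sct, Iigp1, Oasl1, Ifit3, Ifi213, Ifit1, Zbp1 and Rsad2, between 26.3-fold for Ifit2 and 15.2-fold for Rsad2. Of these, the Ifit genes, Oasl1, Zbp1 and Rsad2 are antiviral genes induced by interferon, and Iigp1 is an immunity-related GTPase. Sct, which encodes the gut hormone secretin, rose 25.6-fold (log2 difference 4.68, SE 0.15, adjusted p 4.42e-05). The largest fall was that of Lyz2 (probe set 10372648), the lysozyme gene of myeloid cells, which fell by 4.57 on the log2 scale (SE 0.27, 23.8-fold, adjusted p 0.000302). Hepacam2 fell 18.7-fold, Clec4b2 17.5-fold, Map2k6 13.2-fold and P3h2 10.5-fold. Ms4a1, Ccl6, Serpinb10, Itga8 and Klhl24 fell between 7.56-fold for Ms4a1, which encodes the B cell antigen CD20, and 5.25-fold for Klhl24. Slfn1, Ifit1, Ifi213 and Rsad2 lay below the median probe set in untreated cells and Hepacam2, Clec4b2, Map2k6 and Serpinb10 in infected cells. The folds of these genes are measured against values not told from background. Lyz2 and Ms4a1 also stand among the markers of monocytes and macrophages and of B cells, which are given further below.

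Of 19938 genes tested, 2544 (12.8%) passed an adjusted p of 0.05, of which 1352 rose and 1192 fell. By at least 2-fold, 310 genes rose and 174 fell. By at least 8-fold, 34 genes rose and 5 fell. The groups did not overlap at 50.7% of genes, where chance gives 33.3%. The count rests on limma's pooled variance, since the smallest exact two-sided permutation p for 2 arrays against 2 is 0.333. Without moderation of the variance, on 2 residual degrees of freedom, 1 gene passed. Leaving out MCMV replicate 1 gave 1054 genes and leaving out MCMV replicate 2 gave 954, while the count of 2-fold genes stayed between 452 and 532 whichever array was left out.

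**Figure D1:**
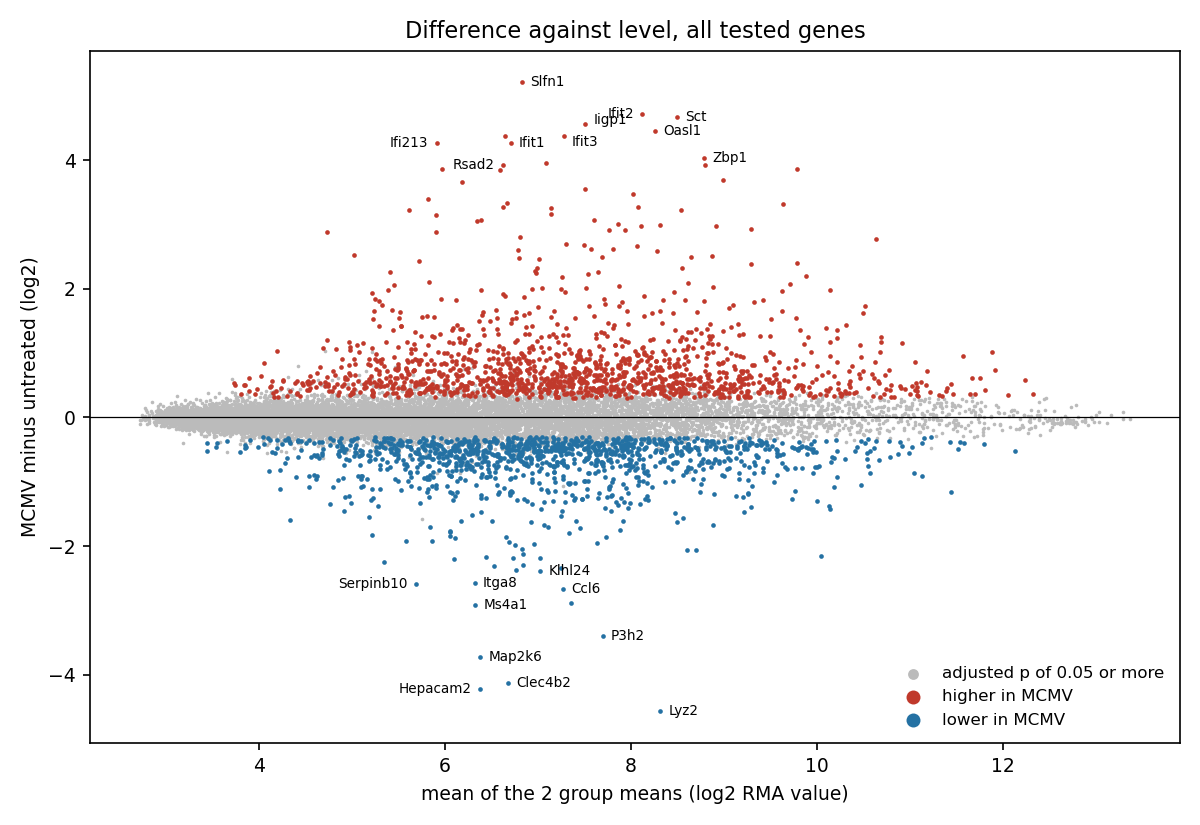
Difference between MCMV and untreated arrays (log2, vertical axis) against the mean of the group means (log2 RMA value, horizontal axis) for the 19938 genes tested. Red points rose and blue points fell at a limma adjusted p under 0.05, and the 10 largest rises and falls of the naming rule are labelled, from Slfn1 at 5.22 to Lyz2 at -4.57.

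Genes induced by type I interferon, the antiviral cytokine family, rose almost without exception. Of 33 members measured, 32 rose and none fell, with a median log2 difference of 2.89. Ifit2 rose by 4.71 (SE 0.08), Oasl1 by 4.46 (SE 0.11) and Ifit3 by 4.39 (SE 0.13). Irf7, the transcription factor that amplifies interferon production, rose 14.6-fold. Irf9, which differed by 0.33 with an adjusted p of 0.0525, was the member that did not pass. Adjusted over the list alone, 33 members rose. The list was shifted upward against all other genes (camera adjusted p 4.83e-49 with the preset correlation; adjusted p = 0.232 with an estimated correlation). With 1 of the 4 arrays left out in turn, 31 or 32 members rose.

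Of 14 GTPases and regulators inducible by interferon-gamma, 11 rose and 1 fell. Iigp1 rose 23.6-fold, Gbp5, a guanylate-binding protein of cell-autonomous defence, 8.45-fold, and the GTPase Irgm1 7.63-fold. Ciita, the transactivator of MHC class II genes, fell by 0.54 (adjusted p 0.0167). Nos2, the inducible nitric oxide synthase, differed by -0.17 and did not pass. The median log2 difference was 1.18, and 11 members rose and 2 fell when adjusted over the list alone. Camera gave an adjusted p of 1.21e-08, against an adjusted p = 0.248 with an estimated correlation. Without MCMV replicate 2 the number that rose was 7, and Ciita passed only in the fit without untreated replicate 1 (adjusted p 0.0651, 0.0647 and 0.124 without untreated replicate 2, MCMV replicate 1 and MCMV replicate 2).

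**Figure D2:**
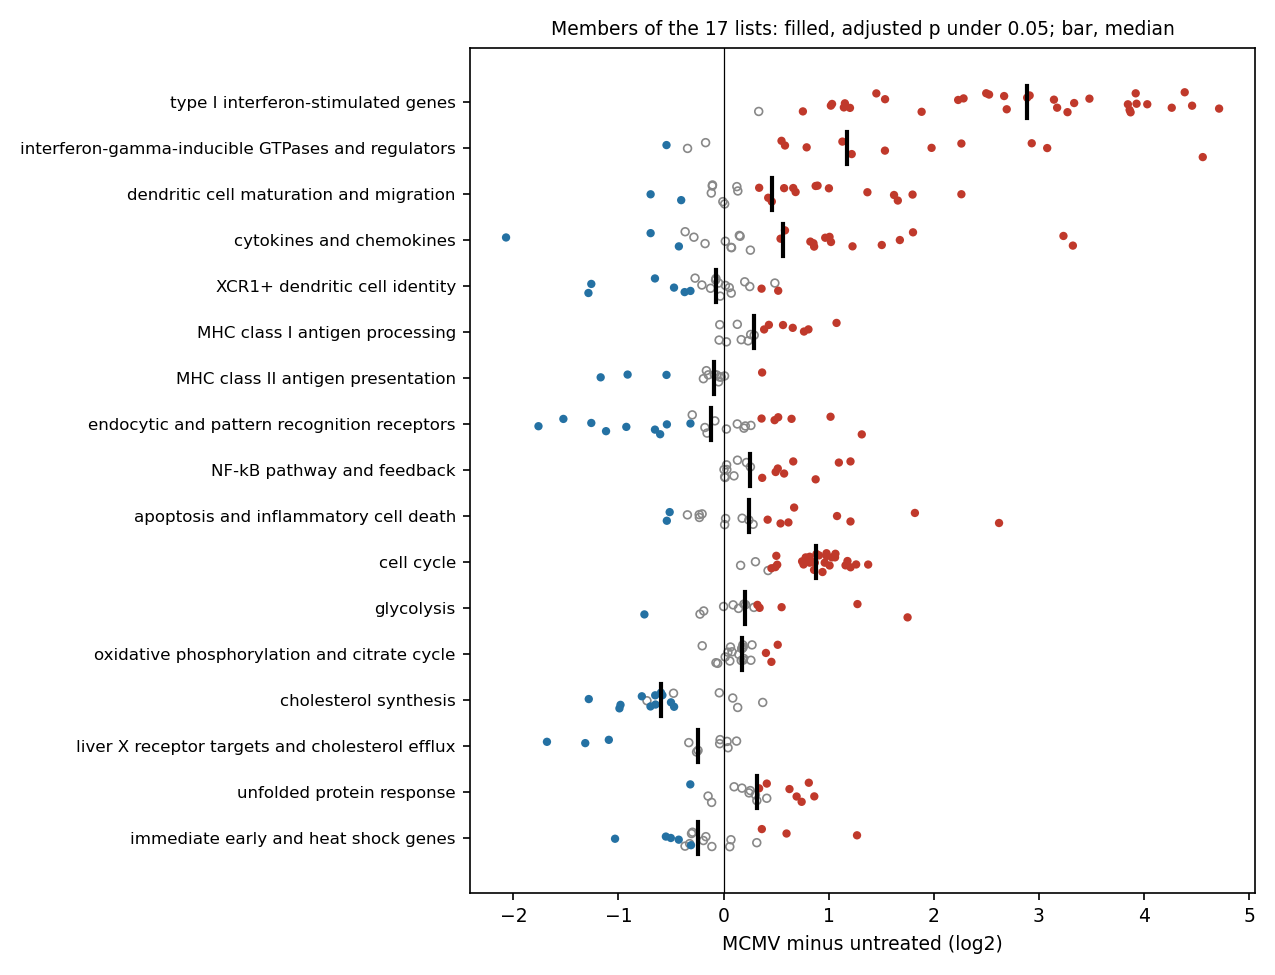
Log2 difference between MCMV and untreated arrays (horizontal axis) for each measured member of the 17 pathway lists (vertical axis). Filled points passed a limma adjusted p of 0.05, red for higher and blue for lower, open points did not, and the bar is the median of the list, which runs from 2.89 for type I interferon-stimulated genes to -0.60 for cholesterol synthesis.

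Of 23 genes of dendritic cell maturation and migration, 14 rose and 2 fell. Cd274, which encodes the inhibitory ligand PD-L1, rose 4.80-fold (log2 difference 2.26, SE 0.17), the costimulatory receptor gene Cd40 3.48-fold (1.80, SE 0.08) and Pdcd1lg2, which encodes PD-L2, 3.16-fold from 4.40, below the median probe set. Ccr7, the receptor that guides dendritic cells to T cell zones, rose 2.58-fold from 9.54 ± 0.11 to 10.91 ± 0.16 (SD, n = 2). The costimulatory gene Cd80 rose by 0.34 (adjusted p 0.0426), a call that ended in each of the 4 fits with 1 array left out (adjusted p 0.0644 to 0.206). Cd86, at 10.53 in untreated cells, differed by 0.13 and did not pass (adjusted p 0.391). Ccl22 and Cd83, both named after their values were seen, fell by 0.69 and 0.40. Camera gave an adjusted p of 1e-06 and an adjusted p = 0.248 with an estimated correlation, and adjusted over the list alone 14 rose and 2 fell. The number that rose was 9 without MCMV replicate 1 and 8 without MCMV replicate 2. The number that fell was 1 without untreated replicate 2 or MCMV replicate 1 and 0 without untreated replicate 1 or MCMV replicate 2.

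Of 26 cytokine and chemokine genes, 14 rose and 3 fell. Cxcl10, a chemokine for activated T and NK cells, rose by 3.32 on the log2 scale (SE 0.09, adjusted p 2.67e-05). Il6 rose 9.41-fold from 3.99, below the median probe set, to 7.23. Il15, a survival factor of NK and memory T cells, rose 3.49-fold, and its receptor gene Il15ra 1.86-fold. Il12b, a subunit of interleukin 12, rose by 0.97 (SE 0.19), with adjusted p values of 0.0646 and 0.0833 without untreated replicates 1 and 2. Ifnb1, which encodes interferon beta, rose by 0.86 within the range below the median probe set, with an adjusted p of 0.0541 without untreated replicate 1. Cxcl9 rose by 0.58 from a high level of 11.95 (adjusted p 0.0551 without MCMV replicate 2). Il1b, an inflammatory cytokine, fell by 2.07 (SE 0.20, 4.20-fold), and Ccl22 and Cxcl16 fell by 0.69 and 0.43, Cxcl16 being named after its value was seen. Ebi3 differed by -0.28 and did not pass. The median log2 difference was 0.56, and adjusted over the list alone 15 members rose and 4 fell. Camera gave an adjusted p of 4.11e-06 and an adjusted p = 0.248 with an estimated correlation. Without untreated replicate 1 or MCMV replicate 2, 1 member fell.

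**Figure D3:**
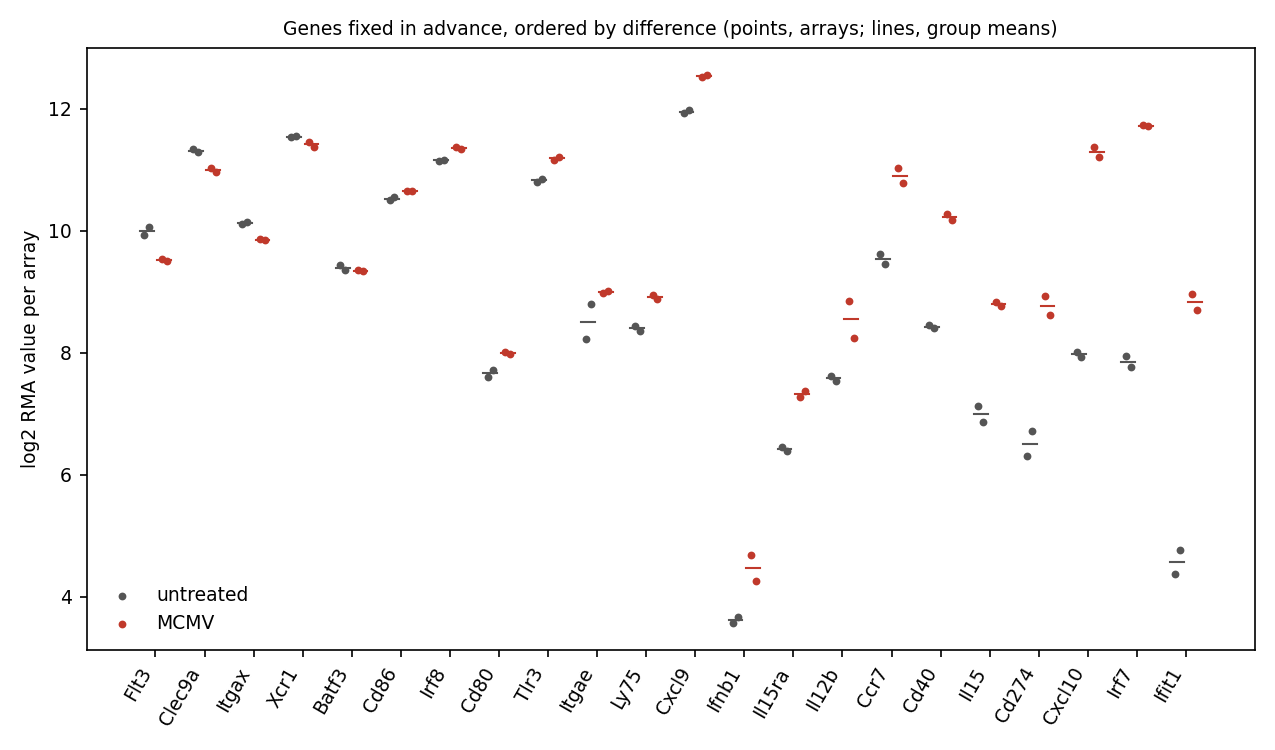
Deposited log2 RMA value (vertical axis) on each array for the 22 measured genes chosen before the data were examined, ordered by their difference. Grey points are the 2 untreated arrays, red points the 2 MCMV arrays and lines the group means, which lie 4.26 apart for Ifit1 and 0.12 apart for Xcr1, where MCMV is the lower (-0.12).

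Genes that identify XCR1+ dendritic cells moved in both directions. Of 21 measured, 2 rose and 6 fell, the median log2 difference was -0.07, and the list did not pass (camera adjusted p 0.156; adjusted p = 0.394 with an estimated correlation). Xcr1 itself (probe set 10597996) stood at 11.54 ± 0.02 in untreated and 11.42 ± 0.06 in infected cells (SD, n = 2; adjusted p 0.423). The transcription factor genes Batf3 and Irf8 differed by -0.05 and 0.20, and Cd8a, whose protein was part of the sort, by 0.07, and none of them passed. Itgae differed by 0.49 with an adjusted p of 0.163. Snx22 fell 2.44-fold, the Toll-like receptor gene Tlr12 2.39-fold and the scavenger receptor gene Cd36 1.57-fold. Flt3, the receptor for the growth factor of dendritic cells, fell by 0.47, with adjusted p values of 0.0615, 0.0928 and 0.116 without untreated replicate 2, MCMV replicate 1 and MCMV replicate 2. Clec9a, a receptor for dead cells, fell by 0.31 and Tlr3, a sensor of double-stranded RNA, rose by 0.36, and neither call held in any of the 4 fits with 1 array left out (adjusted p 0.102 to 0.236 and 0.0728 to 0.164). The endocytic receptor gene Ly75 rose by 0.52, with adjusted p values of 0.0804 and 0.0656 without MCMV replicates 1 and 2. Itgax, which encodes the CD11c of the sort, differed by -0.28 (adjusted p 0.0574). Adjusted over the list alone, 3 identity genes rose and 7 fell, and the list passed downward after quantile normalization (camera adjusted p 0.0192) and with fry (adjusted p 0.0389). With MCMV replicate 1 or 2 left out no identity gene rose, and with untreated replicate 1 left out 1 rose. The number that fell was 3 without untreated replicate 2 and 3 without either MCMV replicate.

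Genes of MHC class I antigen processing rose or did not pass. Of 15 measured, 7 rose and none fell, with a median log2 difference of 0.29. Nlrc5, the transactivator of MHC class I genes, rose 2.11-fold, Tapbpl 1.75-fold and the peptide transporter gene Tap1 1.70-fold. B2m, the light chain of MHC class I, differed by 0.03 at a level of 12.65 in untreated cells. Camera gave an adjusted p of 2.88e-06 and an adjusted p = 0.248 with an estimated correlation, and adjusted over the list alone 10 members rose. Rising members numbered 3 without MCMV replicate 1 and 2 without MCMV replicate 2, and Nlrc5 had adjusted p values of 0.112 and 0.115 in these fits. Of 13 genes of MHC class II presentation, 3 fell and 1 rose. H2-Ob fell by 1.17 and H2-Oa by 0.91, the chains of H2-O, which restrains peptide loading, and Ciita fell by 0.54. The member that rose was the protease gene Lgmn, by 0.37, named after its value was seen. H2-Aa differed by -0.09 at 12.60 in untreated cells and did not pass. Camera gave an adjusted p of 0.0298 and an adjusted p = 0.248 with an estimated correlation, and adjusted over the list alone 1 rose and 3 fell. That camera call ended without untreated replicate 1 (adjusted p 0.101), without MCMV replicate 1 (0.0606) and without probe sets below the array median (0.0717) or the 75th percentile (0.0688), and Lgmn passed in none of the 4 fits with 1 array left out. Ciita did not pass without untreated replicate 2 (0.0651), MCMV replicate 1 (0.0647) or MCMV replicate 2 (0.124).

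Endocytic and pattern recognition receptors moved in both directions. Of 24 measured, 6 rose and 9 fell, and the list as such did not pass (camera adjusted p 0.212; adjusted p = 0.354 with an estimated correlation). The inhibitory Fc receptor gene Fcgr2b fell 3.39-fold (log2 difference -1.76, SE 0.08) and Tlr1, a receptor for bacterial lipopeptides, 2.88-fold. Nod1, a cytosolic sensor of bacterial peptidoglycan, rose 2.49-fold. Tlr13 differed by -0.30 and did not pass. The median log2 difference was -0.12, and adjusted over the list alone 7 rose and 10 fell. With fry the list passed downward (adjusted p 0.0147). The number that rose was 2 without either MCMV replicate.

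Of 17 genes of the NF-kB pathway, the transcription factors of inflammation and their inhibitors, 8 rose and none fell. Cflar, an inhibitor of caspase 8, rose 2.31-fold, Bcl3 2.14-fold and Traf1 1.83-fold, while Rel differed by 0.10 and did not pass. The median log2 difference was 0.26 (camera adjusted p 4.35e-06; adjusted p = 0.248 with an estimated correlation), and 8 members rose when adjusted over the list alone. Rising members numbered 5 without untreated replicate 2 or MCMV replicate 1 and 4 without MCMV replicate 2. Of 19 genes of apoptosis and inflammatory cell death, 8 rose and 2 fell. Casp4, the caspase that senses cytosolic lipopolysaccharide, rose 6.15-fold and Daxx 3.53-fold, while Bak1 differed by 0.28 and did not pass. Aim2 and Pmaip1 fell by 0.54 and 0.51, both named after their values were seen. The median was 0.24 (camera adjusted p 0.00403; adjusted p = 0.248 with an estimated correlation), and the camera call ended when probe sets below the array median (adjusted p 0.0798) or the 75th percentile (0.247) were left out and when camera ran on ranks (0.0677). Adjusted over the list alone, 9 rose and 3 fell. The number that fell was 1 without untreated replicate 1 or MCMV replicate 2 and 0 without untreated replicate 2 or MCMV replicate 1.

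Immediate early and heat shock genes, which respond to stimulation and to handling of cells, did not pass as a list of 18 (camera adjusted p 0.0743; adjusted p = 0.422 with an estimated correlation), with 3 members up, 5 down and a median log2 difference of -0.24. The heat shock genes Hsph1 and Hspa1a rose by 1.27 and 0.60, and the transcription factor gene Egr2 fell by 1.03. Zfp36 differed by 0.07 and did not pass. Hspa8 rose by 0.36, and Btg2, Nr4a1, Egr1 and Egr3 fell by 0.55, 0.50, 0.43 and 0.31, these 5 being named after their values were seen. Adjusted over the list alone, 4 rose and 7 fell. The list passed after quantile normalization (adjusted p 0.0204), after cyclic loess (0.0393), without untreated replicate 2 (0.0281) and without MCMV replicate 1 (0.0407). No member rose without untreated replicate 1, where Hsph1 had an adjusted p of 0.0527 and Hspa1a of 0.0814, and 1 rose without MCMV replicate 1, where Hspa1a had 0.107. The number that fell was 2 without untreated replicate 1 or MCMV replicate 1, 3 without untreated replicate 2 and 1 without MCMV replicate 2.

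Cell cycle genes rose together. Of 30 measured, 27 rose and none fell, with a median log2 difference of 0.88. Bub1, of the mitotic spindle checkpoint, rose 2.60-fold, the S phase cyclin gene Ccne2 2.40-fold and Rrm2, a subunit of ribonucleotide reductase, 2.31-fold. Cdc20 differed by 0.30 and did not pass. Camera gave an adjusted p of 3.12e-21 and an adjusted p = 0.248 with an estimated correlation, which was high for this list at 0.631, and 28 members rose when adjusted over the list alone. The number that rose was 18 without MCMV replicate 1 and 8 without MCMV replicate 2, while the median stayed between 0.80 and 0.99 over the 4 fits with 1 array left out. In those fits Bub1 had adjusted p values of 0.0518 and 0.066 without MCMV replicates 1 and 2, Ccne2 of 0.0658 and 0.131, and Rrm2 of 0.059 without MCMV replicate 2. Within groups the list also differed, by a median of 0.23 between the untreated arrays and -0.20 between the MCMV arrays (replicate 1 minus replicate 2). In the same comparison neutrophil markers had a median of 0.08, NK cell markers of 0.07 and erythroid and platelet markers of -0.03. B cell markers had a median of -0.16 and T cell markers of -0.12. Of 12 neutrophil markers 3 rose, S100a8 by 1.63, S100a9 by 1.45 and Retnlg by 0.39, and 9 did not pass. Of 12 NK cell markers 1 rose, Klrk1 by 1.36, and 11 did not pass. Within groups S100a8 stood at 6.55 and 5.63 on untreated replicates 1 and 2 and at 7.48 and 7.97 on the MCMV replicates.

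Of 14 genes of glycolysis, 5 rose and 1 fell. Pfkp, a phosphofructokinase, rose 3.37-fold and the glucose transporter gene Slc2a1 2.42-fold, and Ldha, Pkm and Pgk1, named after their values were seen, rose by 0.55, 0.34 and 0.32. Pdk1, a kinase that restrains pyruvate oxidation, fell by 0.75, and Hk1 differed by -0.22 and did not pass. The list median was 0.20 (camera adjusted p 0.00403; adjusted p = 0.248 with an estimated correlation). Adjusted over the list alone, 5 rose and 1 fell. Rising members numbered 3 without either untreated replicate and 2 without either MCMV replicate. Pdk1 did not pass without untreated replicate 1 (adjusted p 0.0636), untreated replicate 2 (0.0716) or MCMV replicate 1 (0.0573). Of 22 genes of oxidative phosphorylation and the citrate cycle, 3 rose and none fell, namely Sdhb by 0.52, Cycs by 0.46 and Ndufa9 by 0.40, while Cox6c differed by 0.07 and did not pass. The median was 0.18 (camera adjusted p 0.000926; adjusted p = 0.354 with an estimated correlation), and 3 members rose when adjusted over the list alone. With only probe sets above the 75th percentile of the array, the camera calls of glycolysis and of this list ended (adjusted p 0.053 and 0.0592). Cycs and Ndufa9 did not pass without MCMV replicate 1 (adjusted p 0.0867 and 0.129), none of the 3 without MCMV replicate 2 (0.0821, 0.127 and 0.0893 for Sdhb), and Ndufa9 not without untreated replicate 2 (0.0857). Of 17 genes of the unfolded protein response, 7 rose and 1 fell, with a median of 0.32 (camera adjusted p 3.13e-05; adjusted p = 0.248 with an estimated correlation). The stress transcription factor genes Atf3 and Atf4 rose by 0.86 and 0.81 and Edem1 by 0.74, while Dnajb9, named after its value was seen, fell by 0.32, and Hsp90b1 differed by 0.17 and did not pass. The number that rose was 4 without untreated replicate 2, 2 without MCMV replicate 1 and 3 without MCMV replicate 2. Atf3 did not pass without untreated replicate 2 or MCMV replicate 1 (adjusted p 0.0538 and 0.0999), Atf4 not without MCMV replicate 2 (0.0547), and Dnajb9 in none of the 4 fits. When adjusted over the list alone, 12 members rose and 1 fell.

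Genes of cholesterol synthesis fell. Of 17 measured, 11 fell and none rose, with a median log2 difference of -0.60 (camera adjusted p 5.03e-06; adjusted p = 0.248 with an estimated correlation). Msmo1 fell by 1.28 (SE 0.13), the squalene epoxidase gene Sqle by 0.99 (SE 0.18) and Sc5d by 0.98 (SE 0.08), and Fdps differed by 0.37 and did not pass. When adjusted over the list alone, 13 members fell and 1 rose. The number that fell was 6 without untreated replicate 1, 5 without MCMV replicate 1 and 4 without MCMV replicate 2, and Sqle had adjusted p values of 0.0596 and 0.0981 without untreated replicate 1 and MCMV replicate 2. Without untreated replicate 1, 1 member rose, Fdps by 0.57 (adjusted p 0.0216). Of 11 targets and regulators of the liver X receptors, which sense oxysterols, 3 fell and none rose, and 3 fell whichever array was left out. Apoe, the apolipoprotein of cholesterol efflux, fell 3.21-fold, the desaturase gene Scd2 2.49-fold and Smpdl3a 2.13-fold, while Abcg1 differed by -0.24 and did not pass. The median was -0.24 (camera adjusted p 0.00558; adjusted p = 0.248 with an estimated correlation), and 3 members fell when adjusted over the list alone.

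Markers of other spleen cells were measured beside these groups, since the sort could hold such cells. Of 15 monocyte and macrophage markers, 4 fell and 1 rose, and the list did not pass (median -0.05, mean -0.44, camera adjusted p 0.189; adjusted p = 0.354 with an estimated correlation). Lyz2, Ccr2, Cd14 and Csf1r fell by 4.57, 1.45, 0.96 and 0.50, Csf1r being named after its value was seen, and the last 3 lay below the median probe set in infected cells. Hmox1, which encodes heme oxygenase, rose by 0.81 from 9.60, and Vcam1 differed by 0.16 and did not pass. Without MCMV replicate 1 and without MCMV replicate 2, 2 of these markers fell and none rose. Of 11 B cell markers, 3 fell and none rose (median -0.16, camera adjusted p 0.0168; adjusted p = 0.248 with an estimated correlation). Ms4a1 fell by 2.92, Fcrla by 1.30 and Cd79b by 0.56, and Pou2af1 differed by -0.16 and did not pass. Only Ms4a1 of these 3 passed without MCMV replicate 1 or 2, where Fcrla had adjusted p values of 0.0604 and 0.056, and Cd79b did not pass without untreated replicate 1 either (0.06). Of 9 T cell markers, Cd5 fell by 0.65 and Cd3e differed by -0.20 (median -0.12, camera adjusted p 0.347; adjusted p = 0.438 with an estimated correlation). Cd5 did not pass without MCMV replicate 1 (adjusted p 0.0968) or 2 (0.148). None of 8 markers of erythroid cells and platelets passed in limma, with 1 at an unadjusted p under 0.05 (median -0.03, camera adjusted p 0.736; adjusted p = 0.76 with an estimated correlation), Slc4a1 and Itga2b differing by -0.13 and -0.05. When each was adjusted over the list alone, 2 markers of monocytes and macrophages rose and 4 fell, 4 of B cells fell and 1 of T cells fell.

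Of 8 markers of plasmacytoid dendritic cells, the interferon-producing dendritic cells, 3 rose and 1 fell (median 0.22, camera adjusted p 0.0621; adjusted p = 0.248 with an estimated correlation). Pacsin1 rose by 2.24 (SE 0.08, 4.73-fold), and the transcription factor genes Spib and Tcf4 rose by 0.67 and 0.60. The chemokine receptor gene Ccr9 fell by 1.10, and Cox6a2 differed by 0.31 and did not pass. Spib did not pass without MCMV replicate 1 (adjusted p 0.0518) or 2 (0.0924), nor Tcf4 without MCMV replicate 2 (0.0519), 2 members fell without untreated replicate 2, and the list passed upward after quantile normalization (0.0425) and with fry (0.00612). Of 10 markers of CD11b+ dendritic cells, Cd209a fell by 1.23 to a level below the median probe set and Sirpa by 0.45, and Cx3cr1 differed by -0.18 (median -0.13, camera adjusted p 0.0364; adjusted p = 0.248 with an estimated correlation). Sirpa passed in none of the 4 fits with 1 array left out (adjusted p 0.0566 to 0.126) and Cd209a not without MCMV replicate 2 (0.0566). The camera call ended without untreated replicate 1 (0.067) and without MCMV replicate 2 (0.0929). Of 12 neutrophil markers, the calprotectin genes S100a8 and S100a9 rose by 1.63 and 1.45 and Retnlg by 0.39, the last within the range below the median probe set, and Mpo differed by 0.03 (median 0.08, camera adjusted p 0.0412; adjusted p = 0.248 with an estimated correlation). Only S100a9 of these 3 passed without MCMV replicate 1 or 2, Retnlg not without untreated replicate 1 (adjusted p 0.143), and the camera call ended without untreated replicate 2 (0.0757), without MCMV replicate 2 (0.0519), on ranks (0.0578) and without probe sets below the array median (0.0529). Of 12 NK cell markers, Klrk1, which encodes the activating receptor NKG2D, rose by 1.36 and Tbx21 differed by 0.17 (median 0.07, camera adjusted p 0.0412; adjusted p = 0.248 with an estimated correlation). That camera call ended without untreated replicate 1 (adjusted p 0.124) and without MCMV replicate 2 (0.0724). When each was adjusted over the list alone, 3 plasmacytoid markers rose and 2 fell, 2 markers of CD11b+ dendritic cells fell, 3 of neutrophils rose and 1 of NK cells rose.

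**Figure D4:**
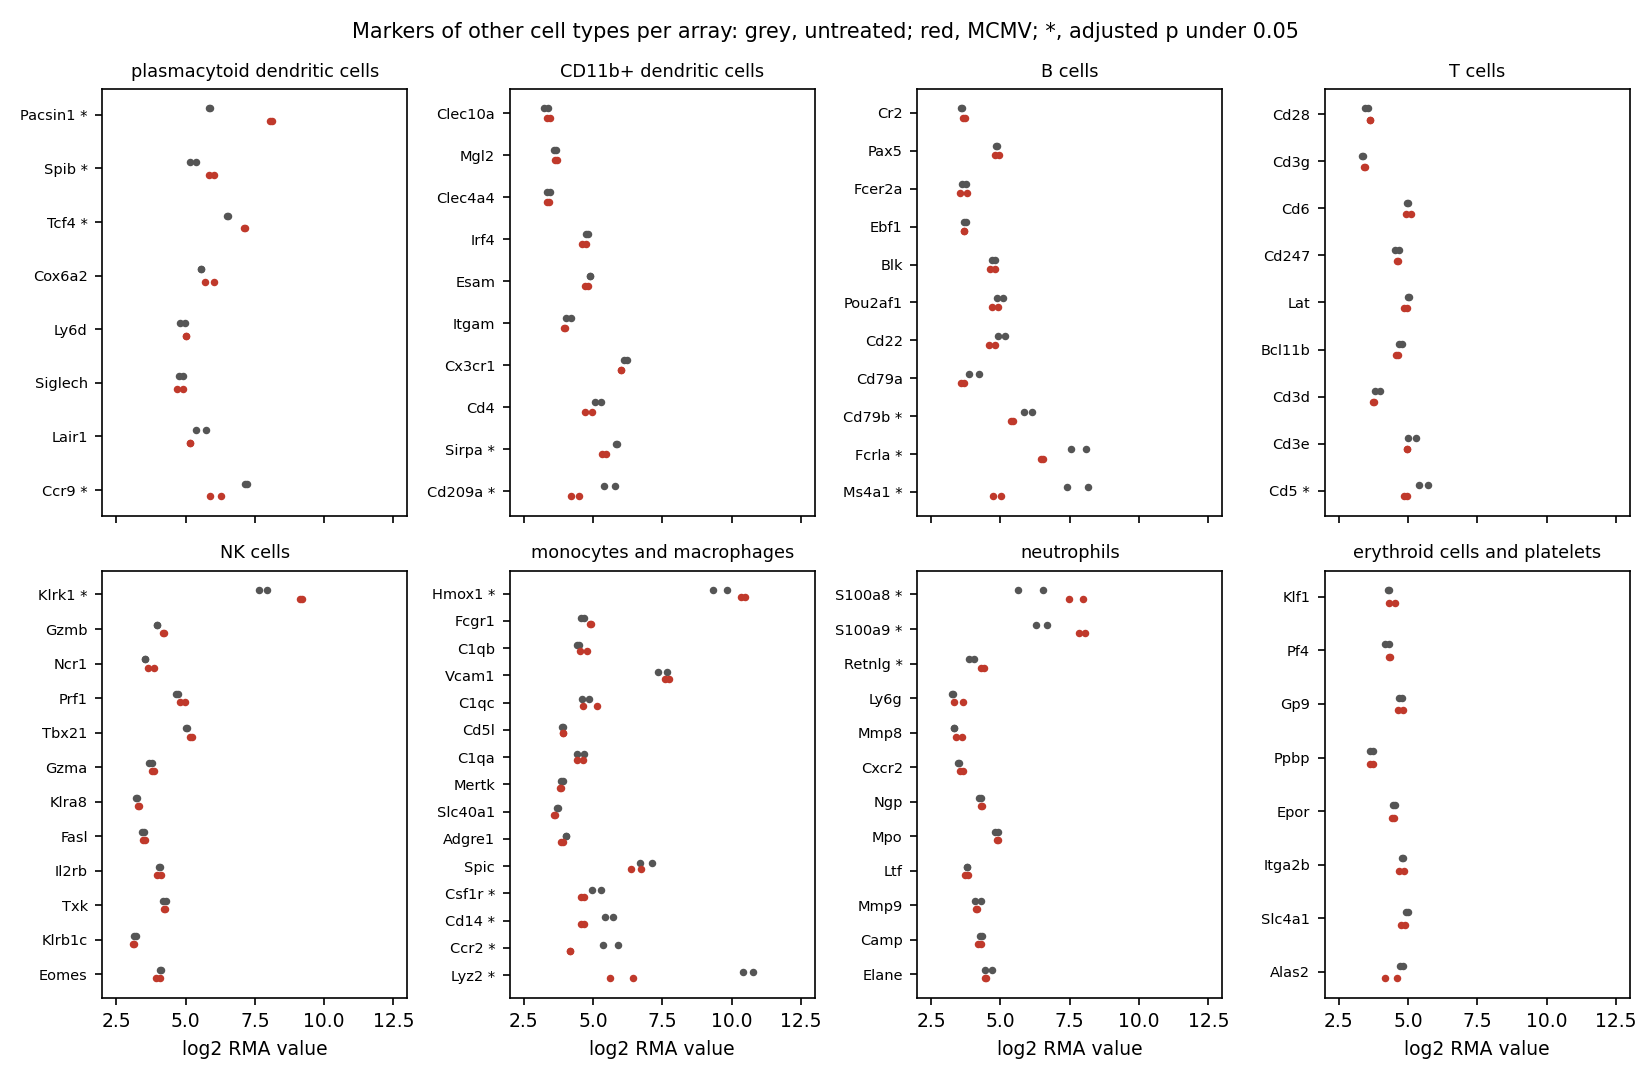
Deposited log2 RMA value (horizontal axis) on each array for the measured markers of 8 other cell types, grey for the 2 untreated arrays and red for the 2 MCMV arrays. An asterisk marks a limma adjusted p under 0.05, as for Lyz2, whose arrays lie at 10.4 and 10.8 untreated and 6.44 and 5.61 with MCMV.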

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

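Signal was also present outside the named genes, in probe sets that the comparison of genes did not use. Of the probe sets that the annotation pairs with several gene symbols, 94 (5.80%) passed a limma adjusted p of 0.05 between MCMV and untreated arrays, 54 of them higher and 40 lower in MCMV. Of the probe sets with no symbol here, 207 (1.70%) passed, 124 higher and 83 lower. These were adjusted over all 35556 probe sets, and no explanation of them was tested.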

How the results depend on the processing

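Of the alternatives, crossed pairing was added after seeing the data. The count of 2544 changed genes lay within 1.5 times under quantile normalization (2693), centring, cyclic loess, both filters, mean probe sets, trended and robust variances (up to 2812) and array weights. It was 1371 when all probe sets were tested singly, 1146 at an adjusted p under 0.01, 341 when treat asked for more than 1.5-fold, and 1 without moderation, where 0 of the 2-fold genes and 0 chosen genes passed. The test without moderation has 2 residual degrees of freedom and the thresholds are stricter by construction, while for the probe sets tested singly the cause was not tested. With 1 array left out, the range was 954 to 1957 genes, 452 to 532 of 2-fold, 15 to 18 lists and 10 to 12 chosen genes, against 484, 18 and 16. Fits with fewer arrays have less power, and 783 genes were called with the same sign in all 4, among them 428 of the 2-fold genes. No gene called was called in the opposite direction by any alternative at gene level. Lists past the threshold were 10 with probe sets above the 75th percentile, where 4 calls ended and 6 lists, 4 of them called otherwise, had under 3 members left and could not be tested (1 list above the array median), 0 with an estimated correlation, and 15 to 21 otherwise. Whether the replicate numbers pair the arrays is not known. Deviations of same-numbered arrays correlated at -0.11 across genes, but each group gives only a single difference between arrays, which cannot decide it. With the replicate block 2040 genes, 485 2-fold genes, 19 lists and 13 chosen genes passed, and the calls of Cd80, Clec9a, Retnlg and Tlr3 ended, while the list of immediate early and heat shock genes passed (adjusted p 0.0371). The crossed pairing as a block gave 2826 genes. Cd80 and Tlr3 also ended under quantile normalization (adjusted p 0.0736 and 0.0524), Cd80 with a variance trend (0.0588) and Clec9a after centring (0.0695). Irf8 passed with a variance trend (0.011), Irf9 after cyclic loess (0.0389) and both filters, Itgax after quantile normalization (0.0349), above the 75th percentile and with a variance trend, and Ebi3 after quantile normalization (0.0301), above the 75th percentile and with a robust variance trend. For these genes the cause was not tested. Of 94 named genes past the threshold, 60 passed in all 4 fits with 1 array left out. Signal over background limits genes below the array median: 129 of the genes that rose lay there in untreated cells.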

Other observations

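Families beyond the fixed lists were grouped by symbol after their values were seen, and the families, the macrophage test, the test by leaving out arrays, the tests of other cycling cells, the tests of untreated levels and the rules for when a median decides nothing were chosen after seeing the data. Of 11 families tested, the Trim (9 of 59 genes up), Clec, Serpinb and Ms4a families did not pass (camera adjusted p 0.433, 0.433, 0.916 and 0.433), and the p values of the others describe families picked for their values. All 9 Schlafen genes measured rose, with a median log2 difference of 1.57, led after Slfn1 by Slfn5 and Slfn8 (limma camera adjusted p 6.38e-14; adjusted p = 0.103 with an estimated correlation), and 8 or 9 rose with 1 array left out. Slfn5os, 1 of the 9 and below the median probe set in untreated cells, lies over Slfn5, so the signals of these genes are not fully separate. Of 8 interferon-activated PYHIN genes with Ifi20x and Ifi21x symbols, from a family that holds DNA sensors, 7 rose. Their median was 1.61 (camera adjusted p 1.4e-11, against 0.103 with an estimated correlation). Aim2, a PYHIN gene outside this grouping by symbol, fell by 0.54. Of 11 poly(ADP-ribose) polymerase genes, 6 rose, led by Parp12 (2.03) and Parp14 (1.88), and Parp8 fell by 0.70 (camera adjusted p 6.17e-06, against 0.127 with an estimated correlation). Of 16 genes of cytosolic aminoacyl-tRNA synthetases, 7 rose and 0 fell, with a median of 0.45 (camera adjusted p 1.99e-08, against 0.266 with an estimated correlation). Fewer of these synthetase genes rose without untreated replicate 2 or without either MCMV replicate. Of 39 proteasome subunit genes 18 rose, a count that was 6 without untreated replicate 2, 2 without MCMV replicate 1 and 1 without MCMV replicate 2, with a median of 0.29 (camera adjusted p 6.38e-14; adjusted p = 0.165 with an estimated correlation).

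Of 8 Cd300 genes, receptors for lipids on myeloid cells, Cd300c2, Cd300c and Cd300a fell by 2.06, 1.99 and 1.30, Cd300e fell by 1.19 and Cd300lf rose by 0.98 from 4.76, below the median probe set, the last not passing without MCMV replicate 2 (camera adjusted p 0.0027; adjusted p = 0.165 with an estimated correlation). In the same comparison 4 of 15 monocyte and macrophage markers fell, among them Lyz2, Ccr2 and Cd14 by 4.57, 1.45 and 0.96. The marker Hmox1 rose by 0.81, and the list did not pass (median -0.05, camera adjusted p 0.189). Ifngr1, the ligand-binding chain of the interferon-gamma receptor, fell from 11.12 ± 0.08 to 8.97 ± 0.06 (SD, n = 2), 4.45-fold with a limma adjusted p of 6.21e-05. Ifngr2 fell by 0.51 (adjusted p 0.0119), while the type I interferon receptor genes Ifnar1 and Ifnar2 differed by -0.02 and -0.01 and did not pass. The genes of cholesterol synthesis and of liver X receptor targets, which textbook regulation by sterols moves in opposite directions, both had negative medians, -0.60 and -0.24, and Ch25h, which makes an oxysterol that lowers synthesis, differed by 0.12 from a level below the median probe set. Of 57 ribosomal protein genes 0 passed in limma and 9 had an unadjusted p under 0.05, while the family passed downward (median -0.09, camera adjusted p 0.000574; adjusted p = 0.127 with an estimated correlation). Without untreated replicate 1, 1 of them fell, and without MCMV replicate 2, 1 rose.

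The fall of Lyz2, Ms4a1, Ccr2 and Cd14 was set against a loss of other cells, which sorting for lineage-negative cells is meant to remove. Red pulp macrophages as carriers of Lyz2 are argued against by the levels of 9 of their transcripts in untreated cells. Their median was 4.46 (95% bootstrap interval over genes 3.88 to 4.74), below the median probe set. C1qa stood at 4.56, C1qb at 4.46 and C1qc at 4.74, where Lyz2 stood at 10.60. Vcam1, also of the 9, stood at 7.51. Hmox1, a marker outside the 9, stood at 9.60 and rose by 0.81. Levels of different probe sets depend on their probes too, so this test is a rough one. The same test leaves B cells as carriers of Ms4a1 open (4.65, 3.79 to 5.28), where Ighm stood at 5.28, Cd79a at 4.04 and Ms4a1 at 7.79 while Fcrl1 fell from 7.85 to 5.81 (adjusted p 0.000137) and Cd37 fell by 0.99 (0.00221), and monocytes as carriers of Lyz2 open (4.27, 3.84 to 8.11). Median log2 differences of macrophage (0.008, -0.089 to 0.205), B cell (-0.162, -0.285 to 0.01) and monocyte transcripts (0.063, -0.116 to 0.607) decide nothing, since only 1 of 9, 4 of 11 and 6 of 14 lay above the median probe set in untreated cells and the others have little room to fall, and the monocyte transcripts went both ways, with Fcgr4 up by 1.37 and Lst1 at -0.78. Loss of B cells or monocytes stays open, as do a small share of macrophages for Ccr2 and Cd14 and a change inside the sorted cells or a subset of them, which was not tested.

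The rise of cell cycle genes was weighed next. Its median does not rest on 1 array, since the lowest median over the 4 fits with 1 array left out was 0.798. The number of members that passed was lower without either MCMV replicate, as given with the list. Cycling cells of another type would have brought their markers, and the medians of erythroid (-0.025, interval -0.125 to 0.092), B cell (-0.163, -0.56 to -0.016) and T cell markers (-0.115, -0.197 to 0.075), none of which rose, argue against these. NK cell and neutrophil markers had medians of 0.071 (-0.006 to 0.213) and 0.083 (-0.04 to 0.305), but Klrk1, S100a8 and S100a9 rose, and S100a8 differed between the arrays of a group in the same directions as the cell cycle genes, so entry of NK cells or neutrophil precursors stays open, although sorting for lineage-negative, CD11c-high, CD11b-negative and CD8α-positive cells is meant to remove both. More cycling among the sorted cells or their precursors may also account for the rise, as a hypothesis that was not tested.

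The rise of Sct and of Pacsin1, Tcf4 and Spib, genes used by plasmacytoid dendritic cells, was set against entry of such cells. Among 12 of their other transcripts the median was -0.079 (-0.184 to 0.19), 7 of them above the median probe set in untreated cells, with Siglech at 4.85 and 4.81 in untreated and infected cells. Members went both ways, from Ccr9 at -1.10 and Cd7 at -1.01 to Cox6a2 at 0.31 and Atp1b1, which rose by 0.37 (adjusted p 0.0273). Entry raises a transcript less where the sorted cells already carry it, as with Mpeg1 at 11.61 and Cd7 at 7.90 in untreated cells. The median therefore does not decide entry. Siglech, Ly6d, Klra17, Upb1, Smim5 and Blnk, at 3.75 to 4.89 in untreated cells, differed by -0.15 to 0.13 and did not pass. Atp1b1, at 4.22, was the low member that rose. For the large rises of Sct and Pacsin1 this argues against entry, although such low values may understate a change. For Tcf4 and Spib entry stays open. A candidate explanation is induction inside the sorted cells, which the design cannot test apart from a rare subset.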
